A study of Rattus norvegicus with 63 samples.

How the data were processed

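Total RNA from rat kidney was measured on Affymetrix expression arrays, on which several short probes for one transcript together make a probe set. The labels place each sample at 0 h, without any injection, or at 1 of 16 times from 0.25 to 72 h after an injection of methylprednisolone, a synthetic glucocorticoid. They name neither the dose, the strain nor the hour of day, and untreated samples exist at 0 h only. The main array type carries 53 arrays and 15923 probe sets, and the second array type carries 10 arrays and 8799 probe sets, with 4 arrays at 0 h, 3 at 2 h and 3 at 6 h.

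The deposited value of each probe set is an intensity on a linear scale, above 0 throughout. The authors scaled each array, as the deposited intensities themselves show: the mean of each array after leaving out the lowest and the highest 2% of its values was between 150.03 and 150.04 on the main type and between 150.19 and 150.23 on the second. The algorithm that turned probe brightness into these intensities is not given in the sources used here. Both array types were scaled separately, so every test was run within 1 table. The median intensity of an array ranged from 65.63 to 83.33 on the main type and from 38.82 to 44.98 on the second. For arrays it is their number that limits the precision, since no read depth exists.

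Values were taken as log2(intensity + pseudocount), with the 10th percentile of each table as the pseudocount, 7.63 on the main type and 3.56 on the second. Differences on this scale understate the change of dim probe sets. Array medians were close under the deposited scaling, which was kept. After removal of the control probe sets (57 and 59), probe sets whose mean log2 level lay at or above the 40th percentile were tested, 9520 on the main type and 5244 on the second. That floor corresponds to a signal of 52.3 on the main type and 25.3 on the second. Arrays a and b of 5 h replicate 1 share a number in the labels and were averaged, which left 52 libraries on the main type: 4 at 0 h and 3 at every other time. No pair of columns held identical values. The log2 values of libraries of the same time correlated with r between 0.853 and 0.974 across probe sets, which are not independent replicates, and arrays a and b of 5 h replicate 1 with r = 0.915.

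Gene symbols came from the platform annotation, updated through gene identifiers with a table of the assembly GRCr8 that was used for names alone. On the main type 12783 probe sets had 1 symbol, 312 had several and 2771 had none listed; on the second type these numbers were 7006, 308 and 1426. Of the symbols on the main type, 12748 were matched by gene identifier, 2 by accession and 33 were kept as the platform gives them. No gene was named from a probe set with several symbols.

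Differences were tested with limma 3.58.1 in R 4.3.3 (linear model per probe set, empirical Bayes moderation with a mean-variance trend), and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. On the main type all 17 times entered 1 fit, so that they shared one estimate of the spread. A moderated F test over the 16 differences from 0 h asked whether a probe set changed at any time. The times were then pooled into 5 windows (0.25 to 1, 2 to 4, 5 to 8, 12 to 18 and 30 to 72 h), each the unweighted mean of its times, and compared with 0 h. The window of 5 to 8 h was also compared with that of 30 to 72 h, which leaves out the 0 h libraries. On the second type 2 h and 6 h were each compared with 0 h. Neither the labels nor the files say that the numbered samples are separate animals, so the p-values measure only the spread between these samples, which may be technical.

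Lists of genes (31 in all: pathways, kidney segments and other cell types that a kidney sample could hold) were tested with camera, which asks whether the genes of a list moved more in one direction than other genes. It was run with a preset correlation of 0.01 between genes and again with the correlation estimated from the data, over lists with at least 4 measured genes, using the brightest probe set of each gene. Of the 31 lists, 29 were testable on the main type and 30 on the second. The markers of adrenal gland and of adipose tissue on the main type, and the podocyte markers on the second, had too few measured genes. The windows, tests, lists, filter and alternatives were fixed before the data were examined.

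Genes were named by a rule fixed at the same time. It used probe sets with 1 symbol, past the threshold and with every library of the window on the same side of the mean of the compared libraries. The compared libraries were those at 0 h, or those of 30 to 72 h where 5 to 8 h was set against them. The 8 largest positive and the 8 largest negative differences were taken for each window, and 12 and 12 for 5 to 8 h. For 5 to 8 h against 30 to 72 h 6 and 6 were taken, and 5 and 5 for each test on the second type. Members of the lists were named besides. Where a gene has several probe sets, the one with the larger difference was taken, and disagreement with the others is stated.

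On the second array type the sample numbers pair the libraries. Deviations from the time means correlated above 0.1 in 9 of 9 pairs of libraries with the same number (0.14 to 0.28), with a mean of 0.215 against -0.081 for pairs with other numbers. The number was tried as a block in the fit. Unless the block is named, values on the second type come from the fit without it, which leaves this pairing out.

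The procedure was tested on simulated data with known changes added to the real mean level of each probe set. Noise was drawn from a normal distribution with the fitted variance, independently for each probe set and library. It thus held no correlation between genes and no libraries that stand apart, so recovery in the real data may be lower. In the simulated comparison of 30 to 72 h with 0 h over 9520 probe sets, 90% of the probe sets changed by a factor of 2 and 100% of those changed by a factor of 4 were recovered. Of those changed by a factor of 1.41, 40% were. In the simulated comparison of 2 h with 0 h on the second type, over 5244 probe sets, 62% of those changed by a factor of 2 were recovered, and in that of 6 h 34%. For a factor of 1.41 these shares were 6% and 14%. The alternatives were other pseudocounts, quantile normalization, no filter or a filter at the 60th percentile, moderation without the trend or made robust, array weights, a fit of each window with 0 h alone, the sample number as a block, arrays a and b of 5 h replicate 1 kept apart, arrays of letter b or c left out, the mean of all probe sets of a gene, and each library left out in turn. A pair was added after the data had been seen: without array a of 5 h replicate 1, and without 6 libraries that stand apart from others of their time. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.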

Results

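Kidney RNA was collected from untreated rats (0 h) and at 16 times from 0.25 to 72 h after an injection of methylprednisolone, a synthetic glucocorticoid. The main array type was hybridised with 52 libraries, 4 at 0 h and 3 at each later time, and the second array type with 4 libraries at 0 h, 3 at 2 h and 3 at 6 h. The comparisons ask which kidney transcripts changed after the injection, when they changed and whether they returned to the level of the untreated rats. Untreated rats were sampled at 0 h only, so elapsed time and hour of day may have changed together. Signals below are intensities scaled per array, differences are on the log2 scale with their standard error, and adjusted p-values are from limma. Each gene named as largest in a window lay on the same side of the 0 h mean in every library of that window. Because all windows share the 4 libraries at 0 h, their differences from 0 h also share those libraries' chance values.

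The first changes came within 0.25 to 1 h, differences from 0 h were most often largest at 4 h, and no probe set passed for the window of 30 to 72 h (limma; 517 at an unadjusted p under 0.05; 1 with array weights). Of the 9520 probe sets tested, a share of 0.05 would reach that unadjusted p by chance alone in any window, and 517 is close to it. The early gene Nfkbia, which encodes an inhibitor of NF-kappaB, went from a signal of 48 at 0 h (SD 0.5 on the log2 scale, n = 4) to 448 at 0.25 h and 1240 at 0.5 h (n = 3 each). It stood at 252 at 7 h and 81.1 at 72 h. Fkbp5, a cochaperone of the glucocorticoid receptor, moved later, from 53.4 at 0 h to 164 at 1 h and 658 at 4 h, with 71.9 at 12 h. Sult1a1, a sulfotransferase that conjugates drugs and hormones, had a signal of 150 at 0 h, 2360 at 5.5 h, 1690 at 18 h and 139 at 30 h. Among genes that fell, Slc16a6, a monocarboxylate transporter, went from 165 at 0 h to 32.9 at 4 h and 128 at 30 h.

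**Figure D1:**
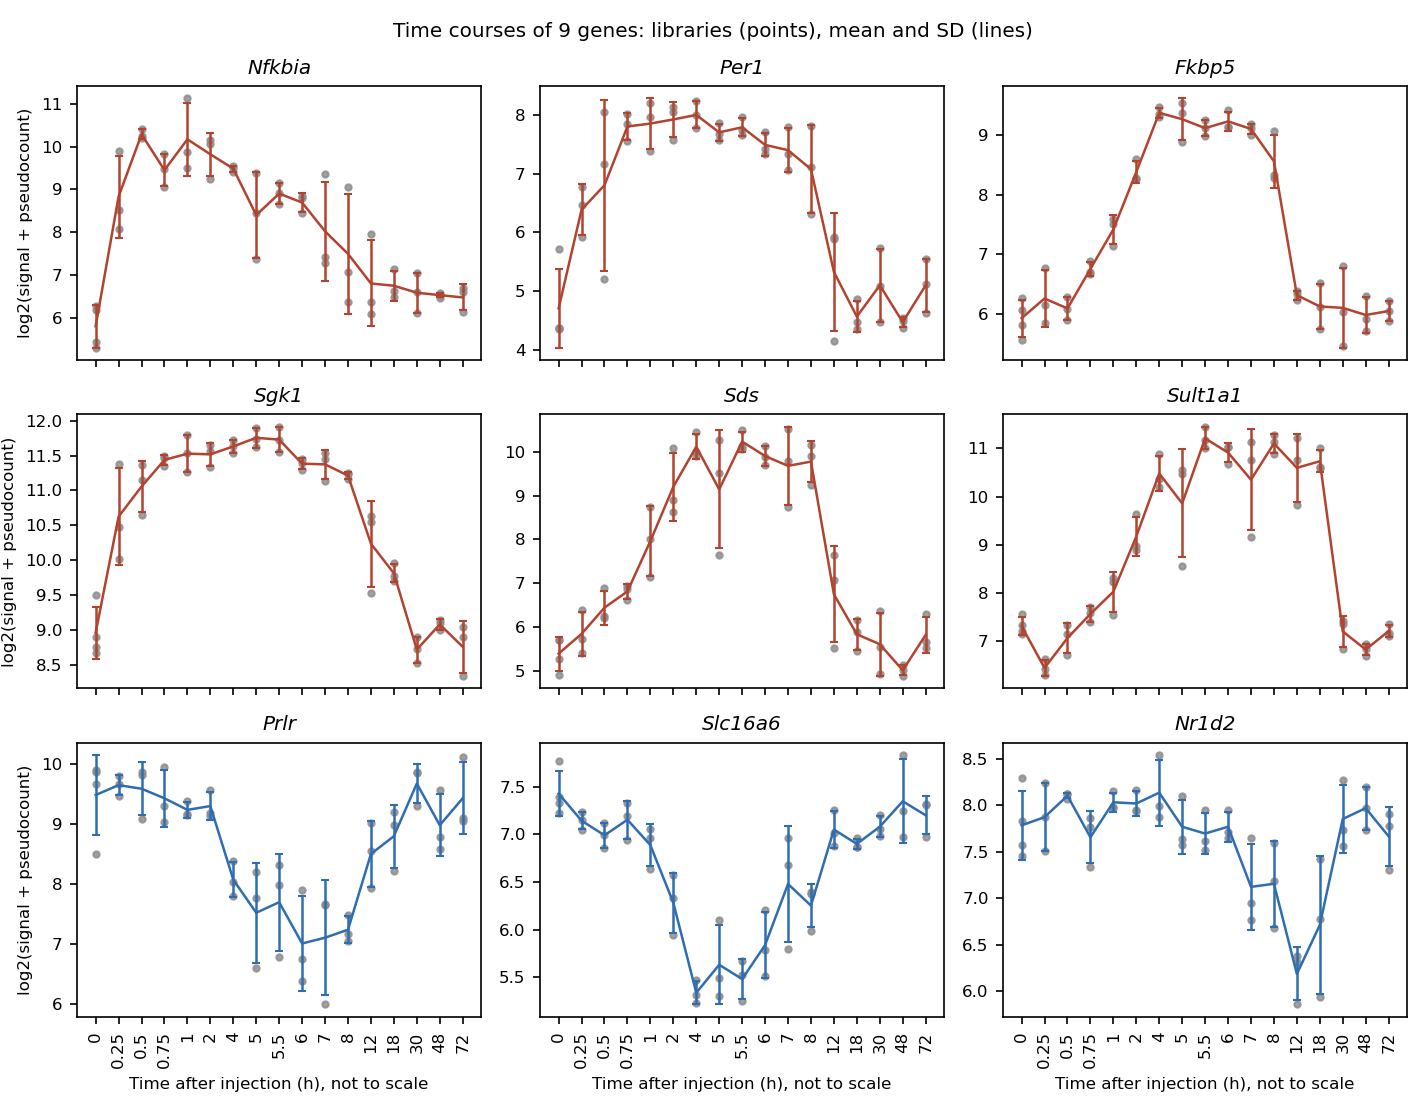
Level of 9 genes, log2(signal + pseudocount), in each of 52 libraries (points) with the mean and SD of each time (lines), against the time after injection in hours, spaced evenly and not to scale. Fkbp5 stood at a signal of 53.4 at 0 h, 658 at 4 h and 58.6 at 72 h, while Slc16a6 stood at 165, 32.9 and 139 at the same times.

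The moderated F test called 1535 of the 9520 probe sets tested (16.1%), from 1245 genes. For these, the largest difference from 0 h came most often at 4 h, where 201 were higher and 179 lower. At 0.25 h it came for 6 higher and 12 lower, and at 72 h for 22 and 22. With array weights the test called 4607, and without the arrays of letter b or c it called 911.

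In the first hour (0.25 to 1 h) 51 genes rose and 4 fell. Nfkbia rose by 3.89 ± 0.37, a 14.8-fold change (adjusted p = 9.48e-10, 12 libraries against 4). Cebpd and Cebpb, transcription factors of the C/EBP family, rose by 3.52 (2 for the other probe set, adjusted p = 0.0051) and 2.45. Zfp36, which destabilises cytokine mRNAs, rose by 2.79, and Ddit4, an inhibitor of mTORC1, by 2.54. Slc25a25, a mitochondrial ATP-Mg/phosphate carrier, rose by 3.01, the dexamethasone-induced GTPase Rasd1 by 2.68 and the clock gene Per1 by 2.5. The 0 h signals of Cebpd, Rasd1 and Per1 (9.58, 13.4 and 18.5) lay near the pseudocount of 7.63, and with 4 times that pseudocount they rose by 2.47, 1.85 and 1.81. The 4 decreases were smaller: Cyp2c11, a cytochrome P450, fell by 1.05, Nsmce3 by 0.72, Hexim1, an inhibitor of the elongation factor P-TEFb, by 0.6, and Unkl by 0.53.

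Of 22 measured genes known to be induced by glucocorticoids, 10 rose (16 adjusted over the list alone), among them Sgk1 by 2.19, Dusp1 by 1.82 and Tsc22d3 by 1.3. Immediate early and stress transcription factors followed: 4 of 12 rose (9 adjusted over the list alone), with Gadd45b at 2.31, Nr4a1 at 1.79 and Klf2 at 0.97. Of 21 cytokines, chemokines and adhesion molecules, 3 rose (10 adjusted over the list alone), namely Il1b by 2.1, Vcam1 by 1.6 and Ccl3 by 1.42. Of 19 heat shock and ER chaperone genes, Herpud1 alone rose, by 1.27 (5 adjusted over the list alone). These 4 lists were called upward by camera with the preset correlation, and they held at adjusted p = 9.22e-09, 0.00085, 0.0276 and 0.0276 with an estimated correlation. A further 5 lists were called with the preset correlation alone. Among extracellular matrix genes 1 of 31 rose, Ccn2 by 2.27 (1 adjusted over the list alone; adjusted p = 0.0763 with an estimated correlation). No macrophage and neutrophil marker passed (4 of 13 adjusted over the list alone; adjusted p = 0.0689 with an estimated correlation). In antigen presentation, ribosomal proteins and oxidative phosphorylation no member passed either way, and the adjusted p with an estimated correlation was 0.435, 0.845 and 0.906.

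Libraries within this window differed widely in acute-phase genes. Fga, which encodes a fibrinogen chain, had a signal of 1580 in 0.25 h replicate 2, 2210 in 0.5 h replicate 3 and 2140 in 1 h replicate 2, against 31 to 616 in the other libraries of the window. The chemokine Cxcl1 lay between 1880 and 2030 in all 3 libraries at 0.5 h and between 9.07 and 164 at 0.75 h. It was 2540 in 0.25 h replicate 2, against 88 and 7.44 in the others of that time. In 1 h replicate 2 it was 3100, against 17.1 and 56.5 in the others. The difference of Cxcl1 in this window, 3.27 ± 1.12, did not pass (adjusted p = 0.314).

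Together 59 probe sets were higher and 4 lower than at 0 h, and 634 had an unadjusted p under 0.05. Leaving out 0 h replicate 2 or replicate 4 left 36 higher, and the lower ones were 0 without 0 h replicate 3 or 4, 1 without 0.75 h replicate 2, 2 without 0 h replicate 2, 0.5 h replicate 2 or 3 or 1 h replicate 3, and 7 without 5 h replicate 2 or 7 h replicate 3. The call of Cyp2c11 was lost without any 1 of 11 libraries, that of Nsmce3 of 10 and that of Unkl of 5, each with the highest adjusted p (0.478, 0.285 and 0.381) without 0 h replicate 3. Hexim1 lost it without 0 h replicate 1, 3 or 4 (adjusted p up to 0.119), Rasd1 without 0 h replicate 2, 3 or 4 (up to 0.121) and Cebpb without 0 h replicate 1 (0.101). With the sample number as a block the calls of Cyp2c11, Nsmce3, Hexim1, Unkl and Rasd1 were lost (adjusted p = 0.104, 0.0977, 0.0636, 0.0696 and 0.0659), and fitted with 0 h alone those of Nsmce3, Hexim1, Unkl and Cebpb (0.121, 0.211, 0.123 and 0.0595). Without the filter on dim probe sets Cyp2c11 and Nsmce3 had adjusted p = 0.0658 and 0.0641, and without the 6 libraries that stand apart Cyp2c11 had 0.078. The list calls of oxidative phosphorylation and ribosomal proteins were lost without 0 h replicate 1 and 4 (adjusted p = 0.755 and 0.299).

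Between 2 and 4 h more genes changed, 407 upward and 357 downward. The fibrinogen genes Fga and Fgg rose by 5.27 ± 1.16 and 4.76 ± 1.19 (adjusted p = 0.00159 and 0.00576, 6 libraries against 4). The other probe set of Fga gave 3.77 (adjusted p = 0.0081). Lcn2, a siderophore-binding protein made by injured tubules, rose by 4.57 ± 0.83. In 2 h replicate 2 Fga had a signal of 523, and the albumin gene Alb one of 793 (median of the libraries 39.4). Spsb1, which encodes a SOCS box protein, rose by 4.51, the serine dehydratase gene Sds by 4.25, Slc25a25 by 3.96, Nfkbia by 3.86 and the insulin-like growth factor binding protein Igfbp1 by 3.82. The 0 h signal of Spsb1, 9.44, lay near the pseudocount of 7.63, and with 4 times that pseudocount Spsb1 rose by 3.35 and Fgg, whose 0 h signal was 19, by 3.87. Among the decreases were Sgk2, a kinase related to Sgk1, by 1.99, the lipase inhibitor G0s2 by 1.86 and Tnfaip8 by 1.82. The receptor Igf2r fell by 1.76, the pyruvate dehydrogenase phosphatase Pdp2 by 1.7, Tril by 1.69 and Slc16a6 by 1.62. Esm1, an endothelial proteoglycan, fell by 1.57.

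Of the 22 glucocorticoid-induced genes, 19 rose (19 adjusted over the list alone), with Fkbp5 at 2.95, Sgk1 at 2.61 and Tsc22d3 at 2.31, and this list held at adjusted p = 5.21e-08 with an estimated correlation. Of 19 chaperone genes 10 rose (13 adjusted over the list alone), among them Herpud1 by 2.52, Hspb1 by 1.49 and Hspa5 by 1.21, with adjusted p = 0.0747 with an estimated correlation. Among the macrophage and neutrophil markers 8 of 13 rose (8 adjusted over the list alone), with S100a9 at 3.65, Cd14 at 1.55 and the complement gene C1qb at 1.49. The 0 h log2 level of S100a9, 4.27, lay under the filter level of 5.91, so the size of its difference depends on the pseudocount. Extracellular matrix genes rose in 6 of 31 cases (9 adjusted over the list alone), with Ccn2 at 3.16, Spp1 at 2.23 and the protease inhibitor Timp1 at 1.96. Cytokines, chemokines and adhesion molecules rose in 4 of 21 cases (7 adjusted over the list alone), with Cxcl10 at 2.42 and Vcam1 at 1.96, and immediate early factors in 4 of 12 cases (6 adjusted over the list alone), with Gadd45b at 3.22 and Jun at 1.12. For these 4 lists the preset calls were lost, at adjusted p = 0.208, 0.144, 0.482 and 0.208 with an estimated correlation. The last 2 of 8 preset calls were those of ribosomal proteins, upward with 1 of 41 members passing (0 adjusted over the list alone), and oxidative phosphorylation, downward with 0 of 83, at adjusted p = 0.66 and 0.697 with an estimated correlation.

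Genes of other kidney cell types fell in small numbers without a call of their list. Of 9 endothelial markers, Kdr, the main VEGF receptor, fell by 1.23, Tie1 by 0.84 and Egfl7 by 0.68, while Esam rose by 1.01 (4 fell and 1 rose adjusted over the list alone). Of 7 podocyte markers, Synpo fell by 0.9, Wt1 by 0.55 and Podxl by 0.52 (3 adjusted over the list alone). In sodium and potassium handling the mineralocorticoid receptor gene Nr3c2 fell by 0.8, the potassium channel gene Kcnj1 by 1 and Kcnj16 by 0.56, and Nedd4l, a ubiquitin ligase that acts on the epithelial sodium channel, rose by 0.74 (2 rose and 3 fell of 17 adjusted over the list alone). With the preset correlation these lists had adjusted p = 0.207, 0.0986 and 0.739.

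In this window 492 probe sets were higher and 457 lower, with 2341 at an unadjusted p under 0.05. The count of lower ones was 273 without 0 h replicate 3, 300 without 0 h replicate 4, 293 without 4 h replicate 2 and 281 without the arrays of letter b or c. With array weights the counts were 1025 and 1378. The call of G0s2 was lost without any 1 of 8 libraries (adjusted p = 0.0798 without 0 h replicate 4), with the block (0.0847), without the filter (0.0569), with robust moderation (0.0515) and without the arrays of letter b or c (0.0988), and the list calls of oxidative phosphorylation and ribosomal proteins were lost without any 1 of 4, up to an adjusted p of 0.302 without 0 h replicate 1 and 0.182 without 0 h replicate 4.

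**Figure D2:**
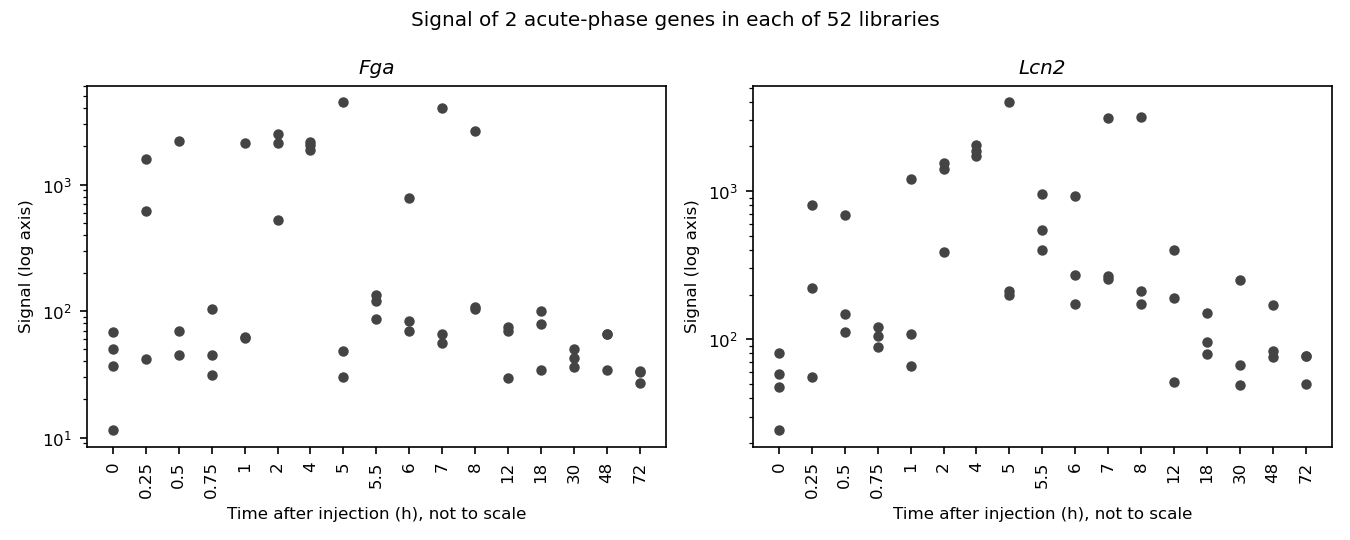
Signal of 2 acute-phase genes (log axis) in each of 52 libraries (points) against the time after injection in hours, spaced evenly and not to scale. Signals of Fga lay between 523 and 2510 in the 6 libraries at 2 and 4 h, and single libraries at 0.25, 0.5, 1, 5, 7 and 8 h reached 1580 to 4460.

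From 5 to 8 h 391 genes rose and 356 fell. Sds, whose product turns serine into pyruvate, was highest at 4.34 ± 0.33, a 20.3-fold change (adjusted p = 5.11e-13, 15 libraries against 4). Sult1a1 rose by 3.38 and the glutathione transferase gene Gstm1 by 2.71. Fkbp5 rose by 3.13 ± 0.17, an 8.74-fold change with adjusted p = 5.04e-18. Other large increases were those of Spsb1 (3.7), Lcn2 (3.2 ± 0.72), Slc25a25 (2.92), Per1 (2.79), Ddit4 (2.72), Ccn2, a connective tissue growth factor (2.63), Sgk1 (2.52) and Nfkbia (2.5). With 4 times the pseudocount Spsb1 and Per1, dim at 0 h, rose by 2.63 and 2.03.

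Among the decreases, Prlr, the prolactin receptor gene, fell by 2.18 ± 0.3, although its other probe sets gave -0.22 (adjusted p = 0.457) and -0.75 (adjusted p = 0.0284). Cldn10, a tight junction gene, fell by 1.48 ± 0.13 (adjusted p = 2.39e-11), the monocarboxylate transporter Slc16a6 by 1.49 and the ion channel gene Trpv1 by 1.55 (other probe set -0.64, adjusted p = 0.016). Tmem86a fell by 1.62, the clock output factor Dbp by 1.56, Igfbp5 by 1.39 and Gclc, an enzyme of glutathione synthesis, by 1.38. C1qtnf3 and Nlrp6 fell by 1.34 and 1.33. Slc2a13, a myo-inositol transporter, fell by 1.34 and Slc34a1, the phosphate transporter of the proximal tubule, by 1.3, but their other probe sets gave -0.35 (adjusted p = 0.161) and -0.1 (adjusted p = 0.62).

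By group, 18 of the 22 glucocorticoid-induced genes rose (22 adjusted over the list alone), and this list alone held, at adjusted p = 2.62e-07 with an estimated correlation. In drug metabolism and glutathione transferases 6 of 25 rose (6 rose and 1 fell adjusted over the list alone), with Por, the electron donor of microsomal P450 enzymes, at 2.1 (preset adjusted p = 0.0203; adjusted p = 0.406 with an estimated correlation); the median of this list was -0.065 and its mean 0.372. Of 17 organic anion, cation and peptide transporters 5 fell (7 adjusted over the list alone), with Slco2a1 at -0.7, Slc22a6 at -0.49 and Slc22a8 at -0.41 (preset adjusted p = 0.00567; adjusted p = 0.339 with an estimated correlation). Of 15 calcium, phosphate and vitamin D genes 4 fell (4 adjusted over the list alone), among them the parathyroid hormone receptor Pth1r by 1.3 and the calcium-sensing receptor Casr by 0.96, with no call of the list (preset adjusted p = 0.106). Among 29 genes of amino acid catabolism 5 rose and 3 fell (7 and 7 adjusted over the list alone): Prodh rose by 1.96, Odc1 by 1.51 and Got1 by 1.26, while Kmo fell by 0.82 (preset adjusted p = 0.256). Gluconeogenesis and ammoniagenesis had 2 of 12 rising (2 adjusted over the list alone), Got1 and Glud1, while Pck1, which encodes the rate-limiting enzyme, stood at 0.24 ± 0.15 (adjusted p = 0.37; list preset adjusted p = 0.222).

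The channel subunit gene Scnn1a rose by 1.23, while Kcnj16 fell by 0.75 and Nr3c2 by 0.53, out of 17 sodium and potassium genes (1 and 2 adjusted over the list alone; preset adjusted p = 0.774). Of 16 proximal tubule markers 5 fell and Cubn rose, by 0.66 (5 and 1 adjusted over the list alone; preset adjusted p = 0.184). Both Mme and Agtr1a fell among 7 renin-angiotensin and vasoactive genes, by 0.76 and 0.61 (2 adjusted over the list alone; preset adjusted p = 0.199). Of the podocyte markers Synpo fell by 0.93 (5 of 7 adjusted over the list alone; preset adjusted p = 0.0107; adjusted p = 0.339 with an estimated correlation). In the clock list Per1 rose by 2.79, Usp2 by 1.62 and Per2 by 0.58, while Dbp and Nr1d1 fell, by 1.56 and 0.8 (4 and 2 of 13 adjusted over the list alone; preset adjusted p = 0.191).

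Macrophage and neutrophil markers rose in 7 of 13 cases (7 rose and 1 fell adjusted over the list alone). S100a9, dim at 0 h, stood at 2.16 and C1qb at 1.42, while Cd68 and Csf1r stood at 0.15 (adjusted p = 0.77) and 0.16 (adjusted p = 0.646). Extracellular matrix genes rose in 5 of 31 (5 rose and 1 fell adjusted over the list alone), with the collagen cross-linking enzyme Lox at 1.65 and Mgp at 1.11. Chaperones rose in 3 of 19 (3 adjusted over the list alone) and immediate early factors in 3 of 12 (3 adjusted over the list alone). These 4 preset calls each went to adjusted p = 0.339 with an estimated correlation. Those of fatty acid oxidation (3 of 23 rose, with Pex11a at 1.45; 3 adjusted over the list alone), ribosomal proteins (0 of 41) and the proteasome (Psma6 of 34; 1 adjusted over the list alone) went to 0.577, 0.691 and 0.533, as adjusted p-values with an estimated correlation. Beside these groups, 3 libraries stood apart from others of their time. In 5 h replicate 2, 7 h replicate 3 and 8 h replicate 1 the signal of Fga was 4460, 4000 and 2650, and that of Lcn2 3970, 3120 and 3160. In the other 12 libraries of the window Fga lay between 30.3 and 778 and Lcn2 between 172 and 959.

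In all 474 probe sets were higher and 450 lower, and 2104 had an unadjusted p under 0.05. Leaving out 0 h replicate 2 or replicate 3 left 298 and 273 lower, and leaving out 0 h replicate 3 gave 7 list calls instead of 11. Fitting this window with 0 h alone left 276 lower and ended the calls of Gclc and Slc34a1 (adjusted p = 0.092 and 0.154); that of Slc34a1 was also lost without 0 h replicate 2, 3 or 4 (adjusted p up to 0.0628) and with the block (0.0638). Without 0 h replicate 3 the lists of fatty acid oxidation and extracellular matrix had adjusted p = 0.077 and 0.108, and without 0 h replicate 4 those of ribosomal proteins and the proteasome 0.34 and 0.0903.

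**Figure D3:**
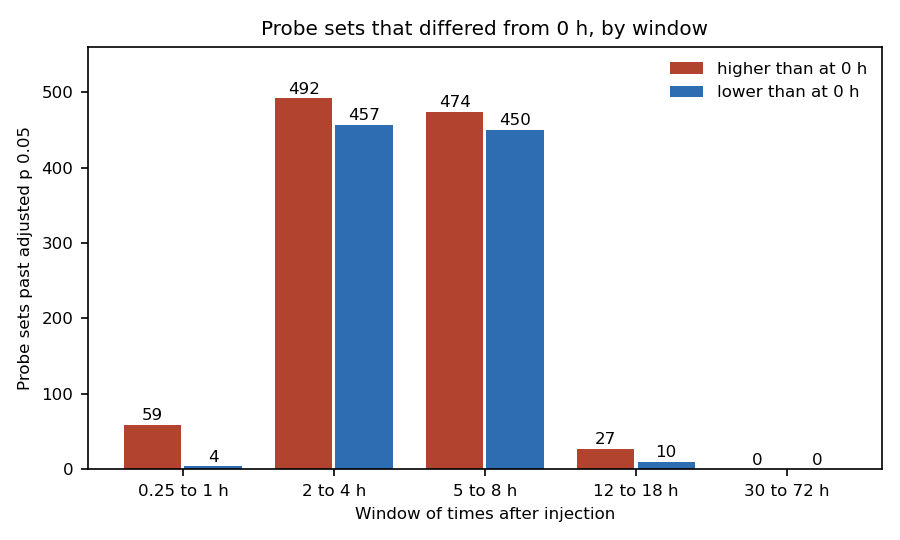
Probe sets past the adjusted threshold of 0.05, higher or lower than at 0 h, out of 9520 tested, in each of the 5 windows of times after injection (bars). The counts were highest at 2 to 4 h (492 and 457) and 5 to 8 h (474 and 450) and 0 at 30 to 72 h (limma; 517 at an unadjusted p under 0.05; 1 with array weights).

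By 12 to 18 h 25 genes were higher and 7 lower than at 0 h. Sult1a1 was still higher by 3.36 ± 0.29 (adjusted p = 1.2e-10, 6 libraries against 4), Gstm1 by 2.54 and Gstm2 by 1.62. Gnmt and Bhmt, which handle methyl groups of methionine and betaine, rose by 2.1 and 1.42, the proline dehydrogenase gene Prodh by 1.98, Apoh by 1.53 and Adh1c by 1.39. Decreases passing the rule numbered 7. Nr1d2, a transcriptional repressor of the clock, fell by 1.34 ± 0.21 (adjusted p = 0.000547), Aadac by 0.99, the kynurenine enzyme Kmo by 0.9 and Tnnc1 by 0.88. Fhit fell by 0.75, Gcnt2 by 0.66 and the class II antigen gene RT1-Da by 0.65.

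Of the 13 measured clock genes Nr1d2 alone passed over all probe sets (1 rose and 5 fell adjusted over the list alone). Dbp stood at -1.55 ± 0.43 (adjusted p = 0.143), Nr1d1 at -0.79 ± 0.22 (adjusted p = 0.146) and Bmal1 at 0.55 ± 0.18 (adjusted p = 0.374). This list was called downward and held at adjusted p = 0.00579 with an estimated correlation. Among glucocorticoid-induced genes 1 of 22 rose, Sgk1 by 1.06 (1 rose and 1 fell adjusted over the list alone; preset adjusted p = 0.0868). The lists of drug metabolism (3 of 25 rose; 3 adjusted over the list alone), gluconeogenesis (0 of 12; 1 adjusted over the list alone) and amino acid catabolism (3 of 29 rose and 1 fell; 3 and 1 adjusted over the list alone) were called upward with the preset correlation. Their adjusted p-values with an estimated correlation were 0.539, 0.735 and 0.735.

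The window gave 27 probe sets higher and 10 lower, with 544 at an unadjusted p under 0.05. Without 0 h replicate 2 these were 13 and 6, and 17 were higher without 0 h replicate 3, 12 h replicate 3 or 18 h replicate 3. The 4 list calls became 8 without 0 h replicate 1 or 2 or 12 h replicate 1, 12 without 12 h replicate 2 and 7 without 18 h replicate 2, while those of drug metabolism and amino acid catabolism were lost without 12 h replicate 3 (adjusted p = 0.0749 and 0.325). Bhmt, Adh1c and Gcnt2 lost their call without 0 h replicate 3, among others (adjusted p = 0.0993, 0.204 and 0.25), Tnnc1 without 0 h replicate 1, among others (0.134), and Aadac without 0 h replicate 2 (0.0586). Fitted with 0 h alone, 5 of the 7 named decreases were lost, Nr1d2 (adjusted p = 0.0724), Kmo (0.0749), RT1-Da (0.0547), Tnnc1 (0.117) and Gcnt2 (0.0764), and so was Bhmt (0.117). Adh1c was lost with the sample number as a block (0.0812), and Tnnc1 without the arrays of letter b or c (0.0772).

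At 30 to 72 h no gene was called against 0 h. Fkbp5 stood at a signal of 61.1, 55.6 and 58.6 at 30, 48 and 72 h against 53.4 at 0 h, and Sult1a1 at 139, 105 and 139 against 150. None of the 22 glucocorticoid-induced genes passed (0 adjusted over the list alone; preset adjusted p = 0.55). Among the macrophage and neutrophil markers none passed over all probe sets and 8 of 13 were higher adjusted over the list alone, for example Lyz2 at 0.64 ± 0.13 and Cd68 at 0.75 ± 0.25. This list was called upward at a preset adjusted p = 2.68e-10 and had adjusted p = 0.159 with an estimated correlation. Ribosomal proteins, oxidative phosphorylation, extracellular matrix and proximal tubule markers were called upward and fatty acid oxidation downward with the preset correlation, with no member passing (0 adjusted over the list alone). Their adjusted p-values with an estimated correlation were 0.53, 0.746, 0.53, 0.53 and 0.612. In limma 0 probe sets passed and 517 had an unadjusted p under 0.05; array weights or leaving out 12 h replicate 1, 18 h replicate 3, 30 h replicate 2 or 48 h replicate 2 gave 1 higher. Without 0 h replicate 3 or replicate 4, 3 lists were called instead of 6. Oxidative phosphorylation was also lost without 48 h replicate 2 (adjusted p = 0.207).

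Set against 30 to 72 h rather than against 0 h, the window of 5 to 8 h gave larger counts, in a comparison of 15 libraries with 9. By the naming rule, the largest positive differences from 30 to 72 h were those of Sds (4.26 ± 0.25), Sult1a1 (3.62), Ccn2 (3.02), Fkbp5 (3.01 ± 0.12), Slc25a25 (2.85) and Sgk1 (2.63). The largest negative ones were those of Prlr (-2.05), Dbp (-2.01), Tmem86a (-1.79), Loxl1, an enzyme of elastin cross-linking (-1.54), Trpv1 (-1.47) and Nlrp6 (-1.47). The other probe sets of Prlr gave -0.14 (adjusted p = 0.4) and -0.46 (adjusted p = 0.0449), and that of Trpv1 -0.93 (adjusted p = 1.03e-06).

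The lists of this paragraph were called with the preset correlation, and except for that of glucocorticoid-induced genes none held: their adjusted p-values ran from 0.244 to 0.532 with an estimated correlation. Of 23 genes of fatty acid oxidation 10 were higher (13 higher and 1 lower adjusted over the list alone), with Pex11a at 1.74, Eci1 at 0.88 and the carnitine palmitoyltransferases Cpt2 and Cpt1a at 0.73 and 0.6. Of 83 genes of oxidative phosphorylation 24 were lower and 2 higher (26 and 2 adjusted over the list alone), by small amounts such as -0.39 for Cox5a and -0.35 for Ndufb3. Organic ion transporters were lower in 9 of 17 cases (9 adjusted over the list alone), with Slc22a6 at -0.65. The same held for 9 of 16 proximal tubule markers (10 adjusted over the list alone; 1 was higher) and for 4 of 8 thick limb and distal tubule markers (4 adjusted over the list alone), with Calb1 at -0.88 and Umod at -0.58. It also held for 5 of 7 podocyte markers (5 adjusted over the list alone), with Synpo at -0.87, and 4 of 7 smooth muscle and pericyte markers (4 adjusted over the list alone), with Tpm2 at -1.04. Calcium, phosphate and vitamin D genes were lower in 8 of 15 cases and higher in 2 (8 and 2 adjusted over the list alone). Of the 13 lists called, that of glucocorticoid-induced genes held (21 of 22 higher; 21 adjusted over the list alone), at adjusted p = 3.72e-06 with an estimated correlation. The other 4 calls, upward, were those of drug metabolism (8 of 25 higher; 8 adjusted over the list alone), chaperones (8 of 19; 10), immediate early factors (6 of 12; 7) and the proteasome (4 of 34, 1 lower; 4 and 1), at adjusted p = 0.248, 0.274, 0.274 and 0.532 with an estimated correlation.

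Here 1188 probe sets were higher and 1309 lower, with 3579 at an unadjusted p under 0.05. Without the arrays of letter b or c, which include 2 of the 3 libraries at 72 h, 629 and 647 passed. The call of the proteasome list was lost without any 1 of 10 libraries (adjusted p = 0.143 without 7 h replicate 3).

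**Figure D4:**
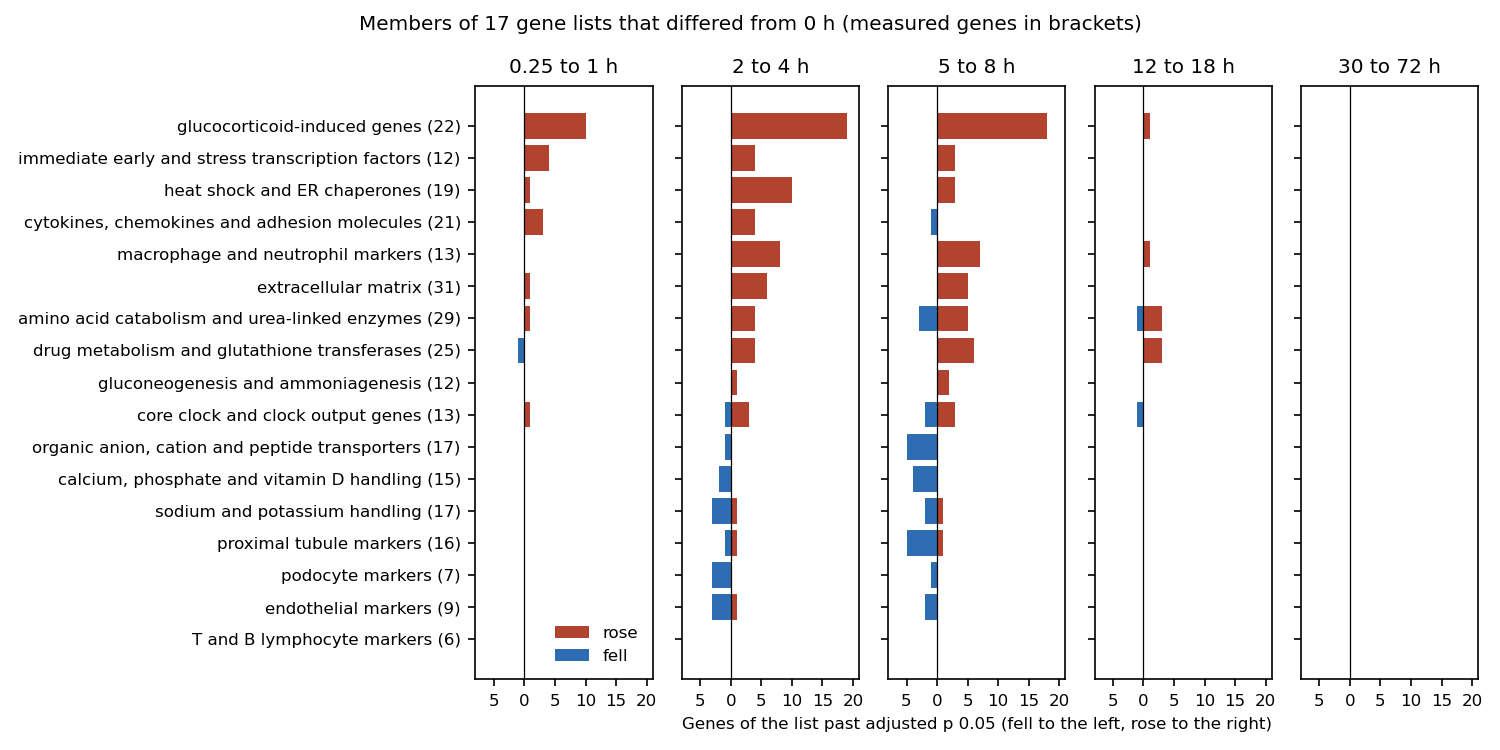
Number of genes of each of 17 lists that rose (right) or fell (left) against 0 h, past the adjusted threshold of 0.05, in each of the 5 windows, with the number of measured genes of the list in brackets. Glucocorticoid-induced genes rose in 10, 19, 18, 1 and 0 of 22 cases.

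At 2 h on the second array type Fgg rose by 5.73 ± 1.04 (adjusted p = 0.00711, 3 libraries against 4), Sds by 5.38, Cebpb by 5.2, the complement gene C3 by 4.85 and Fga by 4.81. In Fgg, Sds, Cebpb and C3 the 0 h signal was 3.94, 2.93, 4.4 and 4.5, near the pseudocount of 3.56, so the size and order of these differences depend on it: with 4 times that pseudocount Fgg rose by 4.47 and Sds by 4.05. The second probe sets of Fgg, Cebpb and C3 gave 2.35 (adjusted p = 0.00807), 3.2 (adjusted p = 0.000682) and 2.62 (adjusted p = 0.00211), and the others of Sds 5.2 and 3.66. Those of Fga gave 3.72 (adjusted p = 0.0379) and 4.49 (adjusted p = 0.0137). Ppil3 fell by 2.47. Pdp2 fell by 2.31. The bone morphogenetic protein gene Bmp4 fell by 2.28. Scd2, a fatty acid desaturase, fell by 2.9 and Cyp2c11 by 2.57, but other probe sets of Scd2 gave -0.54 (adjusted p = 0.551), -0.36 (adjusted p = 0.325) and -1.37 (adjusted p = 0.0199), and that of Cyp2c11 gave -0.65 (adjusted p = 0.189). At 6 h Sds rose by 6.23 ± 0.56 (adjusted p = 0.000108; 4.86 with 4 times the pseudocount), Sult1a1 by 4.72, Cyp2c22, a cytochrome P450, by 3.85, Cebpb by 3.56 (other probe set 2.63, adjusted p = 0.00197) and Igfbp1 by 3.36. Cyp2c22 and Cebpb had 0 h signals of 7.33 and 4.4, and with 4 times the pseudocount they rose by 2.95 and 2.49 at 6 h. Igfbp5 fell by 1.87, Slc16a6 by 1.81, Pter by 1.66 and Trpv1 by 1.61. Prlr fell by 2.98, with 4 other probe sets at -2.08 (adjusted p = 0.0228), -0.41 (adjusted p = 0.814), -0.29 (adjusted p = 0.796) and 0.48 (adjusted p = 0.792), and the other probe set of Igfbp5 gave -1.47 (adjusted p = 0.371).

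Of 13 glucocorticoid-induced genes 8 rose at 2 h and 8 at 6 h (9 and 10 adjusted over the list alone), and the list held at adjusted p = 0.0105 and 0.00191 with an estimated correlation. At 2 h 9 of 15 immediate early factors rose (10 adjusted over the list alone), with Klf6 at 2.99 and Jun at 1.96, and 5 of 7 macrophage and neutrophil markers (5 adjusted over the list alone), with S100a9 at 2.54; these held at adjusted p = 0.0474 and 0.0214 with an estimated correlation. The other 6 of the 9 preset calls at 2 h, all upward, went to adjusted p between 0.134 and 0.427 with an estimated correlation: cytokines (8 of 16 rose; 8 adjusted over the list alone), chaperones (7 of 16; 8), antigen presentation (2 of 13; 2), extracellular matrix (5 of 24; 5), drug metabolism (4 of 26, 1 fell; 4 and 1) and adipose tissue markers (2 of 6; 2). At 6 h the other 6 of 7 preset calls went to adjusted p between 0.0708 and 0.238 with an estimated correlation: drug metabolism (5 of 26 rose; 8 adjusted over the list alone), fatty acid oxidation (1 of 23; 3), gluconeogenesis (1 of 12; 2), macrophage and neutrophil markers (1 of 7; 3), adipose tissue markers (0 of 6; 3) and, downward, organic ion transporters (0 of 15; 0). Of 6 adrenal gland markers 1 rose and 1 fell at 2 h (1 and 1 adjusted over the list alone), with no call (preset adjusted p = 0.73). With the sample number as a block, which pairs the libraries here, fatty acid oxidation at 2 h and extracellular matrix at 6 h were called as well (preset adjusted p = 0.0329 and 0.0144). Without the block these lists had adjusted p = 0.616 and 0.577 with an estimated correlation, which was not run with the block.

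At 2 h 253 of 5244 probe sets were higher and 261 lower, and at 6 h 82 and 41, with 1524 and 559 at an unadjusted p under 0.05. Single libraries moved these counts: the lower ones at 2 h were 131, 90 and 91 without 0 h replicate 2, 3 and 4, 161 without 2 h replicate 2 and 459 without 2 h replicate 3, and the higher ones 152 and 144 without 0 h replicate 3 and 4. At 6 h the lower ones were 21, 23 and 23 without 0 h replicate 2, 3 and 4, 11 and 14 without 6 h replicate 2 and 3, and 86 (with 129 higher) without 2 h replicate 2. At 6 h the call of Prlr was lost without 6 h replicate 2 or 3 (adjusted p up to 0.0773), that of Trpv1 without 0 h replicate 2 or 3 or 6 h replicate 2 (up to 0.103), and that of Igfbp5 without any 1 of 5 libraries (0.113 without 6 h replicate 3). Lists that lost their call were, at 2 h, antigen presentation (adjusted p = 0.166 without 2 h replicate 3), drug metabolism (0.0744 without 2 h replicate 1), extracellular matrix (0.105 without 0 h replicate 3) and adipose tissue markers (0.296 without 2 h replicate 2). At 6 h the organic ion transporters lost theirs (0.0899 without 6 h replicate 1).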

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

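All tests in this part were chosen after the results were seen, except the counts over other splits of the libraries and, for the called clock genes, the share of the 6 h difference kept at 30 h and the tests of 6 h against 30 h; Per1 and Usp2 were singled out afterwards.

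Per1 and Spsb1 stood high in 1 untreated library. At 0 h replicate 2 had a Per1 signal of 44.7 against 12.9, 13.2 and 13.1 in the others, a gap that took up 0.986 of the whole range on the log2 scale with pseudocount, and an Spsb1 signal of 21.1 against 7.77, 6.56 and 5.92, a gap of 0.829 of the range on that scale. The critical value for 4 samples is 0.829, and of 74 groups tested 2 exceeded it, where chance gives about 3.7. The mean log2 level of the 22 glucocorticoid-induced genes in the 4 libraries was 7.52, 7.63, 7.36 and 7.53, and their Sgk1 signal 473, 429, 403 and 720. On array a of 5 h replicate 1 the GAPDH 3'/5' signal ratio, in control probe sets that no comparison uses, was 47.5; the next highest of 52 other arrays was 1.78, the range at 0 h 1.07 to 1.27, and array b of the same number 1.34.

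Acute-phase and injury genes varied between libraries of the same time. Fga was above 1000 in 11 libraries, 5 at 2 and 4 h and 6 at other times. RNA degradation as the source is argued against by the GAPDH 3'/5' ratio, whose deviations within times followed those of 10 acute-phase genes with r = -0.2 (n = 52, p = 0.154, 95% interval -0.449 to 0.0769; 0.169 without the 2 farthest libraries). Liver tissue in the sample as the source is argued against by 10 abundant liver mRNAs, whose deviations within times followed those of the acute-phase genes with a median r of -0.138 (n = 52, bootstrap interval -0.282 to -0.0303; highest 0). It stays open for 2 h replicate 2, where Alb had a signal of 793 against a median of 39.4 over the libraries. Labels swapped with a library of 2 h or 4 h would leave a low Fga signal there, and 0 of those 6 libraries had one under 200. This argues against a swap with the 5 of them above 1000. A swap with 2 h replicate 2 stays open, since its Fga signal of 523 lay under the 778 of 6 h replicate 1. A single wrong label or a swap with an outside sample stays open, and no biological explanation was tested, since the labels name nothing that parts these libraries.

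Clock genes differed from 0 h at 5 to 8 h and at 12 to 18 h, and the hour of day may be a source, if all injections were given at one hour, which the labels do not say. Between 6 h and 30 h, 24 h apart, the median of the 5 called clock genes kept a share of 0.22 of its 6 h difference (bootstrap interval -0.0577 to 0.473), and Per1, Usp2 and Dbp differed by 2.39 ± 0.45, 1.55 ± 0.45 and -1.25 ± 0.54 (adjusted p = 1.9e-05, 0.0035 and 0.0447). These values argue against hour of day alone for Per1 and Usp2. The median share is that of Nr1d1, whose 6 h difference from 0 h was only -0.32 ± 0.26. For Dbp the 6 h difference from 0 h was -0.57 ± 0.51, so hour of day stays open for its fall at 5 to 8 h. Between 6 h and 30 h Per2 and Nr1d1 differed by 0.4 (adjusted p = 0.168) and -0.25 (adjusted p = 0.374), so hour of day stays open for them as well. For the clock genes at 12 to 18 h, 0 times were sampled 24 h later, and drug and hour of day cannot be told apart.

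Of 13 macrophage and neutrophil markers 8 rose at 2 to 4 h and 7 at 5 to 8 h, and the list calls were lost with an estimated correlation (adjusted p = 0.208 and 0.339), while on the second array type at 2 h 5 of 7 rose and the call held (0.0214) and at 6 h 1 of 7 rose and it was lost (0.0708). The rise was not particular to 2 to 8 h. At 30 to 72 h none passed over all probe sets, but 8 of 13 were higher adjusted over the list alone. There the list had a preset adjusted p of 2.68e-10 in camera (0.159 with an estimated correlation). All these windows share the 0 h libraries. More macrophages in the sample and a change of expression within them cannot be told apart. Of the 13 markers 11 were on average higher at 2 to 8 h than at 0 h and 2 lower. Their changes ran from -0.27 for Tyrobp to 1.44 for C1qb and 2.58 for S100a9, which was dim at 0 h. Unequal baselines and other cell sources would also make the changes unequal.

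Chance as the source of the counts was weighed by splitting the libraries otherwise, the real split included. Such splits treat the numbered samples as separate animals, which the labels do not state. They argue against chance for the F test (1 of 100 splits as large, 1535 probe sets against 16 in the highest other split). They also do so, less firmly, at 2 to 4 h (1 of 100, 949 against 780), 5 to 8 h (1 of 100, 924 against 835) and 12 to 18 h (1 of 100, 37 against 9). In every comparison of a window the other splits also mixed the times within it. This can raise their spread within times and lower their counts, an advantage of the real split that has nothing to do with the groups compared. At 0.25 to 1 h the argument is weaker still: 2 of 100 were as large, the real split and 1 with more probe sets (92 against 63). For 5 to 8 h against 30 to 72 h 1 of 100 was as large (2497 against 863). On the second array type 1 of 35 was as large at 2 h (514 against 2) and at 6 h (123 against 1). Among the 7 splits there that part as many numbered pairs, 3, the highest were 0 and 1. So few splits cannot give a share under 0.05, so on the second type chance is argued against only if the pairing by number is left aside. For the 0 probe sets of 30 to 72 h (limma; 517 at an unadjusted p under 0.05; 1 with array weights) the splits decide nothing, since each of the 100 must give at least 0; the highest other gave 8. Chance cannot be excluded for the number of lists called in any window: 10 of 100 splits gave as many at 0.25 to 1 h (9 lists against 12 in the highest other split), 30 at 2 to 4 h (8 against 12), 16 at 5 to 8 h (11 against 18), 66 at 12 to 18 h (4 against 15) and 13 at 30 to 72 h (6 against 11).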

How the results depend on the processing

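The versions without array a of 5 h replicate 1 and without the 6 libraries that stand apart were chosen after the data were seen. Counts given here moved by more than 1.5 times, and the cause was not tested. With array weights the F test called 4607; higher and lower counts were 104 and 42 at 0.25 to 1 h and 1025 and 1378 at 2 to 4 h, 712 were lower at 5 to 8 h, 32 lower at 12 to 18 h and 1 higher at 30 to 72 h. With no filter 2 were lower at 0.25 to 1 h, and 13 lists were called at 2 to 4 h. Fitted with 0 h alone, 276 were lower at 5 to 8 h and 13 higher at 12 to 18 h. With the sample number as a block, 35 were higher and 0 lower at 0.25 to 1 h (limma), and 3 lists were called at 30 to 72 h. Without arrays of letter b or c, which leaves fewer samples, the F test called 911, 281 were lower at 2 to 4 h, 629 higher and 647 lower at 5 to 8 h against 30 to 72 h, and 11 lists were called at 12 to 18 h. Without the 6 libraries 10 were lower at 0.25 to 1 h, 719 at 2 to 4 h and 23 at 12 to 18 h.

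Leaving out 1 library at a time gave 1324 to 1723 for the F test, 36 to 70 higher and 0 to 7 lower at 0.25 to 1 h, 369 to 551 and 273 to 570 at 2 to 4 h, 330 to 517 and 273 to 516 at 5 to 8 h, 13 to 29 and 6 to 14 at 12 to 18 h, 0 to 1 higher and 0 lower at 30 to 72 h, and 1015 to 1229 and 1111 to 1382 at 5 to 8 h against 30 to 72 h. Lists called numbered 8 to 10, 7 to 11, 7 to 12, 3 to 12 and 3 to 8 in the 5 windows. On the second array type 144 to 281 were higher and 90 to 459 lower at 2 h, and 56 to 129 and 11 to 86 at 6 h.

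Of 99 results for named genes none reversed under any alternative in which its probe set was tested. The genes had been named in these data for large differences with every library on one side. A reversal was thus unlikely from the start, and its absence is no further support. With the filter at the 60th percentile only 65 of the results could be compared. Calls were lost for 12 of 67 fitted with 0 h alone, 8 of 99 with the block, 3 of 99 without the filter, 2 of 79 without arrays of letter b or c, 1 of 77 without the 6 libraries, 1 of 99 with robust moderation and 16 of 99 without at least 1 library. None was lost under quantile normalization or the other pseudocounts. Of 234 list results quantile normalization ended 7 calls and made 6, the block 8 and 4 and no filter 0 and 9. Of 174, leaving out arrays of letter b or c ended 5 and made 11, leaving out the 6 libraries 6 and 9, and array weights 4 and 4. Of 67 list calls 21 were lost without at least 1 library. On the main array type 153 of 408 pairs with the same number correlated above 0.1 (mean 0.061 against -0.029 for other pairs). The main fit did not take the numbers to pair the libraries. However, 29 of 52 correlated best with their own number, more than the share of libraries that carry it, so some pairing stays open. On the second type the block gave 211 higher and 243 lower at 2 h and 74 and 33 at 6 h, ended no call of a named gene or list and added those of 2 lists. Dim probe sets, below a signal of 52.3 on the main type, were not tested, and there background limits what can be seen.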

Other observations

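The comparison of the array types was chosen after the results were seen. Genes measured on both array types moved alike at the shared times. Of 2455 such genes, 308 were called on the second type at 2 h, and 277 of these (89.9%) had a difference of the same sign on the main type, against 65.8% of all genes. At 6 h the sign was shared by 76 of 76 called genes (100%, against 70.3% of all genes), and across all genes the differences correlated with r = 0.68 and 0.78. Sds and Sult1a1 rose and Slc16a6 fell at 5 to 8 h on the main type and at 6 h on the second. Cebpb was named as rising on both, but at unlike times: 0.25 to 1 h on the main type, and 2 h and 6 h on the second. The labels do not say whether the 2 types were hybridised with RNA of the same rats, in which case they are not independent.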
